A study of Mus musculus with 8 samples.

How the data were processed

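Small intestinal crypts of 8 mice by label, 4 wild type and 4 miR-29ab1 knockout, were profiled by RNA-seq. RNA was extracted with TRIzol and libraries were made with a strand-marking kit, per the labels' protocols. HISAT2 and DESeq2 are named without versions, per the submitters' processing notes; the read counter, its strand setting, the annotation release and the genome build are not given in the sources used here. Of 55144 gene identifiers shared with GENCODE M21 (GRCm38), 99.5% had identical coordinates, and positions are printed on that build.

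The deposited table gives whole-number counts per gene and library for 55880 genes, per the file headers, of which 28883 had a count in at least 1 library and 409 are unnamed transcripts with identifiers used in that table. The FPKM values the authors deposited are those counts over gene length, scaled by DESeq2 size factors, as checked on the values. The authors' group means, a signal in the deposited table, equal the means of counts over size factors. The log2 fold changes and p-values of the authors' deposited table are quoted only where named. The heat map table the authors deposited holds FPKM of a subset of genes, identical to the whole table.

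Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test with robust dispersion, TMM normalization and filterByExpr, with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of an edgeR log2 fold change is an approximation, its absolute value over the square root of the F statistic of that test. CPM are counts scaled to TMM library sizes, fold values over a floor use total counts, and log2 CPM use a prior count of 2. Before the data were examined, the groups, tests, alternatives, 37 gene lists and the rule for named genes were fixed. The rule takes the genes of the miR-29 locus within 100 kb of Mir29a and Nnt, per list up to 3 members past the threshold or else the 2 with the smallest p, the 12 largest changes per direction among separated protein-coding genes past the threshold with a mean log2 CPM above 1, and the 4 smallest p per direction. The Y-linked genes were named although none passed the filter. Nnt has 2 overlapping records in the table, which share 73425 bases, so its counts are not interpreted.

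Lists with at least 3 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and with an estimated one, with fry, and with exact two-sided permutation tests of list means over the 70 arrangements of 8 libraries, whose smallest p is 0.0286. Adjustment was over the 33 lists tested. 3' UTRs of at least 50 bases from GENCODE M21 were searched for miR-29 seed sites. Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of at least 5 CPM in 4 libraries, a replicate block, protein-coding genes alone, a fold limit and leaving out each library. Chosen after the data were seen were the mean of the enterocyte list as a covariate and the subtraction of 3' UTR length deciles.

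Depth was 13879472 to 17368666 counts per library. Floors of 3 counts for a count of 0 cover counting error alone, since reads carry no molecular identifiers. They cover it for the group at 0 only, and the counts of the other group were taken as they stand. The tests were checked on simulated data with 100 genes changed 2-fold and 100 changed 4-fold. No pair of libraries of one group agreed within sampling noise (chi-square per degree of freedom at least 33.0).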

Results

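RNA from crypts of the mouse small intestine, the epithelial pockets that hold the intestinal stem cells, was sequenced from 8 libraries. The labels put 4 libraries in a wild-type group and 4 in a group lacking the miR-29a and miR-29b-1 genes (miR-29ab1 knockout), all as C57BL/6N mice, before irradiation. Total counts per library ranged from 13879472 to 17368666. The series title names the question as whether miR-29ab acts on intestinal stem cell fate through energy metabolism tied to fatty acid oxidation. The labels name no litter, day or batch, so the p-values of single genes and of permutations measure the spread between these 8 libraries. Camera p-values at the preset correlation of 0.01 treat list members as nearly independent and understate that spread. The median estimated correlation of the lists was 0.338.

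The targeted locus was examined first. Mir29a (chromosome 6, 31062660 to 31062747, minus strand, GRCm38) had 0 counts in every library. Mir29b-1 (31063023 to 31063093, minus strand) had 2 to 7 counts in each library labelled knockout, 17 in all, and 0 in each library labelled wild type. That is 5.89-fold higher over a floor of 3 counts for the wild-type group, without the counting error of the 17. Counts of a deleted hairpin in the knockout group go against the labels taken at face value, so groups are named by label throughout. The extent of the deletion is not given in the sources used here, the hairpin shares 2 bases with the neighbouring gene Gm27019, and mature microRNAs are not measured by these libraries, so the counts do not settle which group lacks the microRNAs. Mir29b-2 and Mir29c, the other members of the family, on chromosome 1, had 0 counts in every library.

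2 neighbouring long noncoding RNAs of this locus rose in the libraries labelled knockout. Lncpint (ENSMUSG00000044471, chromosome 6, 31082565 to 31220488, minus strand), a noncoding RNA known as a p53 target, rose 184-fold (95% interval 140 to 241), from 0.775 ± 0.109 CPM in the wild-type group to 144 ± 24.7 CPM in the group labelled knockout (SD, n = 4 each). Its log2 fold change was 7.52 with an SE of 0.20 (edgeR quasi-likelihood test, adjusted p = 2.29e-07). The interval is a normal approximation from that SE and is narrower than the edgeR test itself would give. Gm27019 (ENSMUSG00000097998, 31063092 to 31063495, minus strand), an annotated noncoding RNA next to the Mir29b-1 hairpin, had 227 to 327 counts in each library labelled knockout and 0 in each library labelled wild type, 380-fold higher over a floor of 3 counts for the wild-type group (edgeR adjusted p = 3.86e-04). The 2 genes lie 19069 bases apart. Gm13833, annotated on the opposite strand inside Lncpint, had 12 counts in the group labelled knockout and 8 in the wild-type group, and whether strand was used in the counting is not given in the sources used here. Gm13835, a processed pseudogene inside the span of Lncpint, had a log2 fold change of -0.13 (SE 0.17, edgeR adjusted p = 0.994), and its value ran from -0.26 to 0.012 when single libraries were left out.

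**Figure D1:**
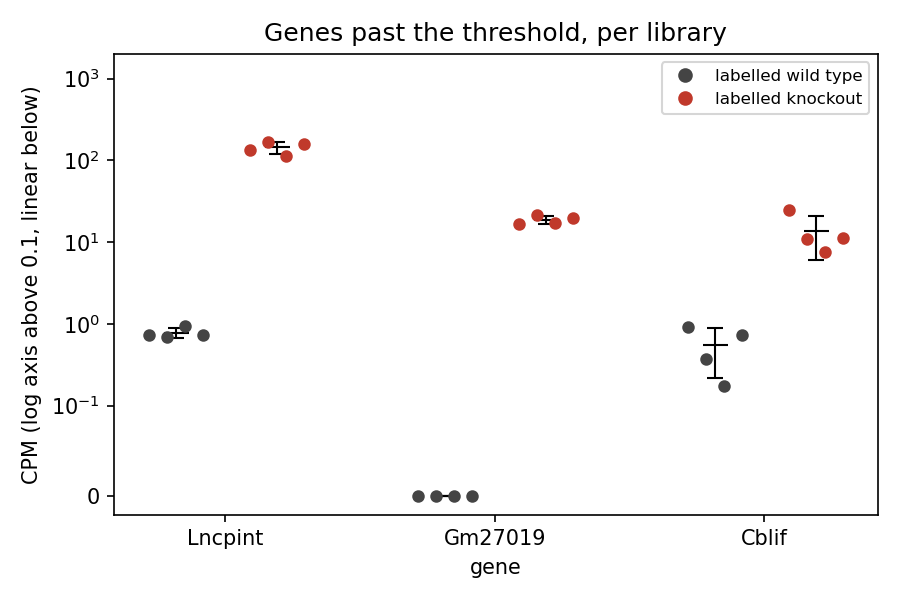
CPM, counts scaled to library size (log axis above 0.1, linear below), of the 3 genes past the threshold, with one point per library and bars for the mean and SD of each group of 4. The 4 libraries labelled knockout lie above the 4 labelled wild type for each gene, and Gm27019 is at 0 in all 4 libraries labelled wild type.

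Across all genes, the comparison of the groups asked which transcripts differ with the label. Of 14897 genes tested, 3 changed, all higher in the libraries labelled knockout and none lower. The third was Cblif (ENSMUSG00000024682, chromosome 19, 11747554 to 11763447), the gene of gastric intrinsic factor, which binds vitamin B12. Cblif rose 24.4-fold (95% interval 11.8 to 50.5 by the same normal approximation). It went from 0.553 ± 0.338 to 13.6 ± 7.48 CPM (SD, n = 4 each, edgeR adjusted p = 0.0496). Its call sat at the threshold and was lost in 7 of the 8 fits that left out one library, where the log2 fold change ran from 4.16 to 4.98 against 4.61 with all 8.

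The count of 0 lower genes comes from edgeR; at an unadjusted p under 0.05 the test gave 278 higher and 124 lower genes, 402 in all, where chance alone gives 745. DESeq2 called 22 genes, 19 higher and 3 lower, and limma-voom called 2, both higher. The authors' deposited table holds 21 genes with an adjusted p under 0.05, 18 higher and 3 lower, and all 21 are among the 22 DESeq2 calls. Among genes called by DESeq2 and not by edgeR, Pdk4, an inhibitory kinase of pyruvate dehydrogenase, had a log2 fold change of 3.06 (SE 0.69, edgeR adjusted p = 0.994), an 8.35-fold ratio. It was at 230 CPM in labelled knockout replicate 4, 22.8 to 81.1 in the other 3 libraries of that group and 7.78 to 15.4 in the wild-type group, and its log2 fold change was 2.07 without labelled knockout replicate 4. Trp53inp1, a stress gene induced by p53, had 0.93 (SE 0.17, edgeR adjusted p = 0.758). Tm4sf1, a membrane protein gene, had -3.05 (SE 0.66, edgeR adjusted p = 0.994). It was low in both groups, at 0.169 ± 0.175 CPM in the group labelled knockout and 1.37 ± 0.403 in the wild-type group (SD, n = 4 each). On simulated counts of the same genes, edgeR recovered 36% of 2-fold and 84% of 4-fold changes with 10 false calls, and DESeq2 57% and 94% with 49 false calls. Those counts were drawn independently for each gene, so these rates do not give the power or the false calls of the real comparison. Groups that did not overlap were found for 228 genes, 1.53% of those tested, where chance gives 2.86%.

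The authors' deposited heat map table holds 670 genes, which are exactly those with an unadjusted p under 0.05 in the authors' deposited table, 446 higher and 224 lower. Because the table was chosen on these libraries, its directions are not independent evidence. Of its genes, 459 passed the expression filter and 3 passed the edgeR threshold over all genes. Adjusted over the list alone 55 passed, but that count is no evidence, because the list was chosen by p on these libraries. Of the 459, 374 had an unadjusted edgeR p under 0.05.

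Fatty acid oxidation, the pathway named in the title, was tested with 28 enzymes and transporters. None of the 28 rose or fell, 10 had a log2 fold change above 0 and 18 below, and 0 passed adjusted over the list alone. The median was -0.013 (camera adjusted p = 0.721), the mean 0.032, and the test direction was down, so the mean differed in sign from the median and the test. Acad9, an acyl-CoA dehydrogenase, had a log2 fold change of -0.31 (SE 0.17) and Acaa1a, a peroxisomal thiolase, 0.51 (SE 0.31), both with edgeR adjusted p = 0.994; without labelled knockout replicate 4 they were -0.19 and 0.17. The list mean was 6.80 ± 0.22 log2 CPM in the group labelled knockout and 6.79 ± 0.18 in the wild-type group (SD, n = 4 each; exact permutation p = 0.971). The median moved between -0.096 and 0.071 when single libraries were left out.

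The crypt base columnar stem cells list, the markers of the cycling Lgr5 stem cells, had 18 members tested, none past the threshold, and 12 above 0. Its median was 0.087 (camera adjusted p = 0.721, and adjusted p = 0.904 with an estimated correlation; exact permutation p = 0.914 for the list means, n = 4 each). Lgr5 had a log2 fold change of 0.31 (SE 0.26) and Rgmb 0.26 (SE 0.25), both with edgeR adjusted p = 0.994; without labelled knockout replicate 1 they were 0.043 and 0.068. This list turned on single libraries: without labelled knockout replicate 4 its median was 0.24 and the camera adjusted p 5.19e-05, without wild type replicate 1 it was 0.14 with 0.0290, and without labelled knockout replicates 1 or 3 it was -0.054 and -0.049. Neither call held with an estimated correlation (adjusted p = 0.67 and 0.728 with an estimated correlation).

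The published miR-29 targets list, which includes collagen and DNA methyltransferase genes, had 27 of 42 members tested, 17 above 0 and none past the threshold. Among those too low to test were the collagen genes Col1a1, Col1a2, Col4a1, Col4a2, Col5a1, Col5a2 and Col5a3, and Eln, Fbn1, Nid1, Lox and Loxl2. The median of the tested members was 0.12 (camera adjusted p = 0.0630, adjusted p = 0.507 with an estimated correlation, and exact permutation p = 0.143, n = 4 each). Lamc1, a laminin chain, had a log2 fold change of 0.72 (SE 0.24) and Dnmt3a, a DNA methyltransferase, 0.26 (SE 0.13), both with edgeR adjusted p = 0.994. The list was called with limma-voom (camera adjusted p = 0.0448) and 4 other settings, and none of these calls held with an estimated correlation (adjusted p = 0.481 to 0.655 with an estimated correlation). It was also called without wild type replicate 1 (median 0.21, camera adjusted p = 0.0165), wild type replicate 2 (0.10, 0.0417) or labelled knockout replicate 4 (0.0089, 0.0358). In these 3 fits it was not called with an estimated correlation (adjusted p = 0.235, 0.742 and 0.67 with an estimated correlation). The list means differed by 0.156 log2 CPM, and by 0.144 without labelled knockout replicate 4.

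Genes whose 3' UTR holds the miR-29 seed site TGGTGCT, 2080 of the 12379 genes searched, had a median log2 fold change 0.020 above that of the 10299 genes without it (camera p = 0.218, and p = 0.0861 with an estimated correlation). The exact permutation p was 0.0857 on the library means and 0.229 on medians (n = 4 each). By the difference of medians, 725 of 5772 heptamers found in a similar number of 3' UTRs lay as high or higher. For the longer site TGGTGCTA, in 410 genes, the difference was 0.033 (camera p = 0.0333), and the exact permutation p was 0.0286 on library means, the smallest that 70 arrangements can give, but 0.171 on medians. Median 3' UTR length was 2590 bases with the 7-base site and 1164 without.

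Of the other lists, 16 of all 33 tested were called by camera with a preset correlation of 0.01, 7 up and 9 down, and none with an estimated correlation (smallest adjusted p = 0.507). None was called with an estimated correlation without any 1 of the 8 libraries either (smallest adjusted p = 0.0917). No member of any list, 438 genes in all, passed the threshold over all genes. Adjusted over the list alone, 2 Wnt targets (Notum and Nkd1) and 1 gene each of the PPAR (Pdk4), T cell (Trdc), proximal intestine (Cybrd1) and p53 (Trp53inp1) lists passed.

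Genes of the cell cycle had a median of -0.32 over 26 members, 25 of them below 0 (camera adjusted p = 1.02e-08, and adjusted p = 0.507 with an estimated correlation). The list mean of labelled knockout replicate 4 was 4.75 log2 CPM against 5.71 on average in the other 7 libraries. The cell cycle call held without each single library, with a median of -0.13 without labelled knockout replicate 4 and -0.51 without labelled knockout replicate 3. Mcm7, a subunit of the replicative helicase, had -0.34 (SE 0.18, edgeR adjusted p = 0.994), and -0.19 without labelled knockout replicate 4. Paneth cell genes, of the antimicrobial cells at the crypt base, had a median of 0.45 over 18 members (camera adjusted p = 1.30e-04, and adjusted p = 0.507 with an estimated correlation), with Defa21, a defensin, at 2944 ± 1778 against 1121 ± 525 CPM (SD, n = 4 each). Without labelled knockout replicate 2 the Paneth call was lost (median 0.058, camera adjusted p = 0.173), and Defa21 had a log2 fold change of 0.88 against 1.39 with all libraries. Wnt target genes had a median of 0.12 (camera adjusted p = 0.00737, and adjusted p = 0.526 with an estimated correlation). Notum, a secreted Wnt inhibitor, was at 2.13 (SE 0.54) and Nkd1 at 1.09 (SE 0.29), both with edgeR adjusted p = 0.994. Notum was low, at 1.80 ± 1.14 CPM in the group labelled knockout and 0.407 ± 0.176 in the wild-type group (SD, n = 4 each). The Wnt list shares members with the crypt base columnar stem cells list, Lgr5 among them. The Wnt call was lost without labelled knockout replicate 1 (median 0.024, camera adjusted p = 0.171) or 3 (0.13, 0.163). It held with medians of 0.064 and 0.21 without wild type replicate 2 and 1, and 0.28 without labelled knockout replicate 4. Tuft cell genes had a median of -0.50 (camera adjusted p = 0.0116, and adjusted p = 0.698 with an estimated correlation). The tuft call was lost without wild type replicate 3 (median -0.48, camera adjusted p = 0.126) or 4 (-0.25, 0.439) and without labelled knockout replicate 3 (-0.59, 0.0725) or 4 (-0.29, 0.413). The tuft median was -0.81 without wild type replicate 1 and -0.88 without labelled knockout replicate 2.

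Among metabolic lists, fatty acid and sterol synthesis had a median of -0.29 over 22 members, 19 below 0 (camera adjusted p = 4.37e-07, and adjusted p = 0.507 with an estimated correlation), with Me1, malic enzyme, at -1.88 (SE 0.58) and Idi1, of isoprenoid synthesis, at -0.64 (SE 0.22). Oxidative phosphorylation had a median of -0.17 over 29 members (camera adjusted p = 2.85e-04, and adjusted p = 0.638 with an estimated correlation). The TCA cycle had -0.14 over 16 (camera adjusted p = 0.0122) and glycolysis -0.18 over 17 (camera adjusted p = 0.00189), both with adjusted p = 0.507 with an estimated correlation. PPAR regulators and targets, which include genes induced by fasting, had 0.18 over 21 (camera adjusted p = 0.0122, and adjusted p = 0.638 with an estimated correlation), with Angptl4 at 2.38 (SE 0.74). Angptl4 was at 275 CPM in labelled knockout replicate 4, 21.3 to 49.5 in the other 3 libraries of that group and 13.8 to 28.0 in the wild-type group, and its log2 fold change was 1.03 without labelled knockout replicate 4. Ketone body metabolism was not called (median -0.19, camera adjusted p = 0.107), with a median of -0.072 without labelled knockout replicate 4, -0.12 without wild type replicate 4 and -0.30 without labelled knockout replicate 3. The fatty acid and sterol synthesis list kept its call without each single library, with medians of -0.40 to -0.20. Without wild type replicate 4, calls were lost for oxidative phosphorylation (median -0.090, camera adjusted p = 0.0952), glycolysis (-0.11, 0.0937) and the TCA cycle (-0.11, 0.132). The TCA cycle call was also lost without wild type replicate 2 (-0.13, 0.0704) or labelled knockout replicate 2 (-0.11, 0.0690), and the glycolysis median was -0.28 without wild type replicate 1. The PPAR call was lost without wild type replicate 1 (0.013, 0.25), labelled knockout replicate 1 (0.15, 0.10) or labelled knockout replicate 4 (0.0089, 0.269), and the median was 0.32 without labelled knockout replicate 3.

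Markers of immune and red blood cells also stood among the called lists. T cell genes had a median of -0.43 over 11 members, all below 0 (camera adjusted p = 2.66e-06), B and plasma cell genes -0.87 over 7 (0.00189), myeloid genes -0.39 over 8 (0.0270) and red blood cell genes 1.47 over 4 (0.00183), each with adjusted p = 0.507 with an estimated correlation. Interferon response genes had a median of 0.81 over 15 members (camera adjusted p = 0.0195, and adjusted p = 0.856 with an estimated correlation), with a list mean of 6.50 log2 CPM in labelled knockout replicate 4. Without that library the interferon response list turned to a median of -0.25 (camera adjusted p = 4.27e-04, and adjusted p = 0.67 with an estimated correlation), and without wild type replicate 3 or 4 or labelled knockout replicate 3 the call was lost (0.189, 0.0952 and 0.0725). p53 targets had 0.28 over 14 (camera adjusted p = 0.0116, and adjusted p = 0.507 with an estimated correlation) and immediate early and heat shock genes 0.68 over 11 (camera adjusted p = 0.0245, and adjusted p = 0.628 with an estimated correlation).

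Single libraries moved these lists too. The T cell call held without each of them, with a median of -0.12 without wild type replicate 1 and -0.76 without labelled knockout replicate 4. The B and plasma cell call was lost without wild type replicate 2 (median -0.076, camera adjusted p = 0.475) or labelled knockout replicate 3 (-0.63, 0.139), and the red blood cell call without labelled knockout replicate 4 (0.53, 0.0913). The myeloid call was lost without wild type replicate 2 (-0.046, 0.311) or 3 (-0.28, 0.147) and without labelled knockout replicate 2 (-0.37, 0.0620), 3 (-0.36, 0.157) or 4 (-0.50, 0.0545), and the median was -0.61 without wild type replicate 4. The p53 call was lost without wild type replicate 4 (0.21, 0.0735), labelled knockout replicate 1 (0.18, 0.120) or labelled knockout replicate 2 (0.26, 0.0777), and held with a median of 0.14 without labelled knockout replicate 4. The immediate early and heat shock call was lost without wild type replicate 1 (0.42, 0.195) or 4 (0.36, 0.377) and without labelled knockout replicate 2 (0.32, 0.173) or 4 (0.20, 0.451).

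The remaining lists were not called. Enterocyte genes, of the absorptive cells of the villus, had a median of 0.36 (camera adjusted p = 0.0767, and adjusted p = 0.904 with an estimated correlation). They were called up without wild type replicate 2 (median 0.45, camera adjusted p = 0.0127), wild type replicate 4 (0.33, 0.0379), labelled knockout replicate 1 (0.43, 0.0396) or labelled knockout replicate 3 (0.65, 2.54e-06), and down without labelled knockout replicate 4 (-0.20, 0.0480). In these 5 fits the estimated correlation gave no call (adjusted p = 0.696 or more with an estimated correlation). MHC class II genes were called up without wild type replicate 1 (0.58, 0.00282) or labelled knockout replicate 2 (0.53, 0.00125), and enteroendocrine genes down without labelled knockout replicate 3 (-0.23, 0.00679). These 3 calls did not hold either (adjusted p = 0.542, 0.563 and 0.678 with an estimated correlation). With all 8 libraries, medians were 0.072 for enteroendocrine genes, where the mean was 0.031 and the test direction down, and -0.10 for goblet cell genes, where the mean was 0.019 and the direction up. They were -0.071 for reserve and injury-induced stem cell genes (mean 0.19), -0.0066 for the Notch pathway, 0.11 for the DNA methylation machinery (0.072 without labelled knockout replicate 4), -0.18 for the 3 endothelium genes tested (-0.38 without wild type replicate 4 to -0.0061 without labelled knockout replicate 4), -0.039 for the proximal intestine (mean 0.0088) and 0.098 for the distal intestine. They were 0.30 for MHC class II, 0.43 for the epithelial antimicrobial and type 2 response, 0.066 for the circadian clock and -0.11 for the unfolded protein response (mean 0.0012). Under the replicate block the epithelial antimicrobial and type 2 response was called down, against a median of 0.23 (camera adjusted p = 0.0318, and adjusted p = 0.655 with an estimated correlation). 4 lists had fewer than 3 members tested. Their summed CPM in the labelled knockout and wild-type groups was 14.9 ± 2.05 and 23.0 ± 18.7 for stroma, 3.98 ± 0.856 and 2.89 ± 1.03 for enteric neurons and glia, and 6.02 ± 1.2 and 6.33 ± 0.229 for exocrine pancreas (SD, n = 4 each; exact permutation p = 0.686, 0.171 and 0.686). The stroma value of the wild-type group rested on wild type replicate 1, at 50.3 CPM, and was 13.8 without it. Of the sex-linked list, Xist was at 1099 and 1163 CPM, and Ddx3y, Uty, Kdm5d and Eif2s3y had 0 counts in every library.

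**Figure D2:**
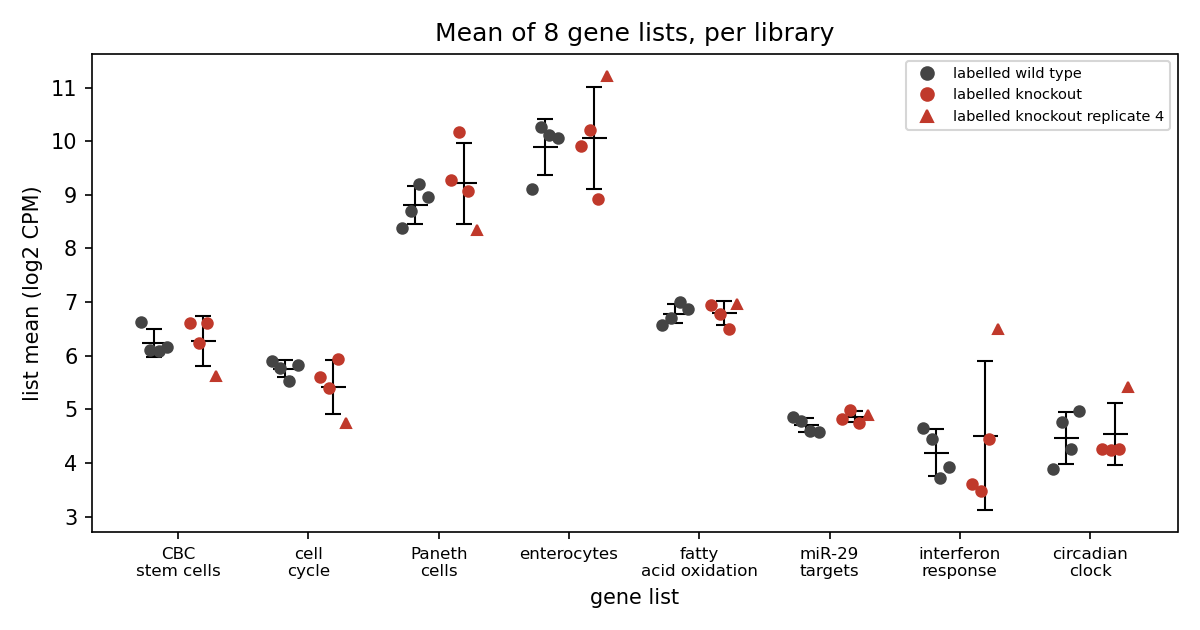
Mean log2 CPM of 8 gene lists, with one point per library, bars for the mean and SD of each group of 4, and a triangle for labelled knockout replicate 4. That library is the lowest for stem cells (5.62), cell cycle (4.75) and, by a small margin, Paneth cells (8.34 against 8.38 in wild type replicate 1). It is the highest for enterocytes (11.2), interferon response (6.50) and the circadian clock (5.41).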

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

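The tests of p53 targets and of the lists of labelled knockout replicate 4 were chosen only after the results were seen. The account of 3' UTR length, on which the test of exchanged labels rests, and the enterocyte covariate were also chosen after the data were seen.

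In 14 of 238 groups of 4 values, 5.88 per 100, one library stood far from the other 3 by the share of the group's range that its gap took (Dixon's 95% critical value), where chance gives about 1 in 20; that share is given in parentheses. Wild type replicate 1 stood out high for the crypt base columnar stem cell list (0.881), the enteroendocrine list (0.930), Lgr5 (0.876), Lamc1 (0.887) and Snap25 (0.833), and low for Pik3r2 (0.872) and Slc10a2 (0.830). Wild type replicate 3 was high for the goblet cell list (0.919). Labelled knockout replicate 4 was high for the circadian clock list (0.990), at 5.41 log2 CPM against 4.25 to 4.26 in the other 3, and for Cry2 (0.850), Irf7 (0.917) and Saa1 (0.839). Labelled knockout replicate 2 was low for the TCA cycle list (0.893) and labelled knockout replicate 3 for Apoc3 (0.867).

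The rise of Lncpint and Gm27019 at the locus said to be deleted may come from the engineered allele itself, which reads would have to show and which was not tested. General p53 activity was judged by the median log2 fold change of 14 p53 targets, 0.277 with an SE of 0.132 over the genes. The median lay below the bound of 1, but that bound was set after the results were seen, so this decides nothing about p53 activity. A p53 response stays open, with 11 of the 14 genes above 0 and 3 below. The SE carries no spread between libraries. An exchange of the group labels stays open. Genes with the 7-base miR-29 site lay 0.0130 higher in the libraries labelled knockout after 3' UTR length was accounted for. Genes with the 8-base site lay 0.0251 higher. That is the direction that correct labels would give, but the exact permutation p was 0.0571 for each site. Flanking DNA that shifts neighbouring genes stays open too, since 49 genes within 5 Mb lay at percentile 76.8 of 10000 expression-matched random sets, between the bounds set.

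The list shifts and the position of labelled knockout replicate 4 were weighed together. That library lay beyond 2 SDs of the other 7 in 3 of 4 lists in the direction that more differentiated villus epithelium would give (enterocytes 2.60, stem cells -2.83, cell cycle -4.76), while Paneth genes lay at -1.35, so the mixture remains a candidate explanation. Without that library 10 of the 16 called lists kept call and direction, and with the enterocyte list as a covariate 11 of 16 did, both between the bounds set, so neither is shown to make the calls or to be without part in them. Chance cannot be excluded for the number of lists: 4 of 35 splits of the libraries gave 16 or more, the highest of the others 19, and every split gave at least 8. With an estimated correlation no split gave any.

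For genes changed, 2 of the 35 splits gave as many as the real split's 3, the other with 4, so chance cannot be excluded for the count. That other split holds 2 libraries of each label on either side, so its direction is arbitrary, and in such splits the larger of the counts up and down was taken for genes higher and for genes lower alike. By that choice 2 of 35 splits gave as many genes higher, 3 against the same 4 genes, and chance is not excluded for that count; if those 4 were counted as lower, the real split would stand alone. For genes lower, all 35 splits gave at least the real 0, the highest other being again those 4, which decides nothing because no count can be below 0. For the heat map genes 1 of 35 splits gave 3 and the others 0, which decides nothing because those genes were chosen on the real split.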

How the results depend on the processing

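The enterocyte covariate and the 3' UTR length correction were chosen after the data were seen, and the other settings were planned. Lncpint kept its call in all 15 settings that tested it, with log2 fold changes of 7.43 to 7.63, and Gm27019 in 14 of 15, losing it under the replicate block. Cblif kept its call in 5 of 16, with log2 fold changes of 4.16 to 4.98 and adjusted p from 4.85e-16 to 0.330. DESeq2 called 22 genes, 19 higher and 3 lower, 22 of them in the heat map table and 7 among the named genes. Without a filter 5 genes were called, all higher and all 5 in the heat map table. With protein-coding genes alone 0 were called, of any kind, and 0 at the locus, since both noncoding genes leave the test. Cblif stayed in that test and lost its call. The cause of the other differences was not tested. The values gave no sign that replicate numbers pair the libraries: same-number correlations were 0.07, 0.03, -0.39 and -0.09. No wild-type library correlated best with the labelled knockout library of its own number. This cannot exclude a shared litter or day. The replicate block called 2 genes, 1 of them at the locus, and 17 lists, gaining the epithelial antimicrobial and type 2 response (down, against a median of 0.23). The number of called lists fell from 16 to 0 with an estimated correlation and to 0 with fry, and ran from 10 (without wild type replicate 4) to 17 when single libraries were left out. Calls were lost with limma-voom for tuft, myeloid, interferon and immediate early genes, without a filter for the last and myeloid genes, with the stricter filter for Wnt targets, with protein-coding genes alone for B and plasma cells, under the block for interferon, and with the covariate for tuft, PPAR, myeloid, interferon and immediate early genes. The published miR-29 targets list gained a call with limma-voom (0.11), the stricter filter (0.12), the replicate block (0.12), protein-coding genes alone (0.12) and the enterocyte covariate (0.13), and without wild type replicate 1, wild type replicate 2 or labelled knockout replicate 4. Its median ran from 0.0089 to 0.21 with single libraries left out, and no setting called it with an estimated correlation. The same ranges were -0.054 to 0.24 for the crypt base columnar stem cells list and -0.096 to 0.071 for the fatty acid oxidation list. For the miR-29 seed site, at a difference of 0.020 from genes without it, camera gave p = 0.218, while fry, which tests the genes with a site against no change and not that difference, gave p = 0.0388, the 8-base site gave 0.033 with camera p = 0.0333, and subtracting length deciles gave 0.013 and 0.025, both with exact permutation p = 0.0571. Camera with an estimated correlation gave p = 0.0861 for the 7-base site and p = 0.0276 for the 8-base site. Signs turned with no call on either side for the unfolded protein response list (0.033 with limma-voom, 0.052 with the replicate block, 0.026 with the covariate) and for Slc10a2 (-0.32, -0.39 and -0.33 in that order). With the covariate they turned for the Notch pathway list (0.0082), the distal small intestine list (-0.16) and the circadian clock list (-0.065). Leaving out single libraries turned the sign of more list medians, the interferon response among them from a call up to a call down without labelled knockout replicate 4, with these ranges: MHC class II -0.22 to 0.58, Notch pathway -0.078 to 0.12, circadian clock -0.27 to 0.31, distal small intestine -0.46 to 0.66, enterocytes -0.20 to 0.65, enteroendocrine cells -0.23 to 0.17, epithelial antimicrobial and type 2 response -0.14 to 0.56, goblet cells -0.12 to 0.14, interferon response -0.25 to 1.19, proximal small intestine -0.36 to 0.012, reserve and injury-induced stem cells -0.13 to 0.12 and unfolded protein response -0.23 to 0.14. Of named genes not past the threshold, it turned Cd74 (-0.060 to 0.53), Cela1 (-0.18 to 0.016), Cry2 (-0.25 to 0.89), Cubn (-0.030 to 0.96), Gm13835 (-0.26 to 0.012), H2-Aa (-0.29 to 1.12), Ifit3 (-0.51 to 2.17), Irf7 (-0.16 to 1.32), Saa1 (-0.14 to 3.27), Slc10a2 (-1.74 to 1.54), Snap25 (-0.092 to 0.41) and Vim (-0.79 to 0.064). Of all tests under other settings, 91 lost a call, 24 gained one and 46 turned sign; of counts, 9 fell and 8 grew by over 1.5 times. The cause was not tested. At this depth and spread edgeR recovered 36% of 2-fold changes in counts simulated independently for each gene, which does not give the power of the real comparison.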

Other observations

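Which genes stood apart within the groups was looked at beyond the comparisons, and the search for genes on in some animals and off in others was set after such genes had been noticed.

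Labelled knockout replicate 4 had the highest interferon and clock list means of all 8 libraries, with Irf7, a regulator of the interferon response, at a gap of 0.917 from its group. Its first principal component score was 72.6, where the other 7 ranged from -38.6 to 12.2, and that component held 33.5% of the variance. Xist was high and the Y-linked genes at 0 in every library, a profile of female tissue.

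A hypothesis was linked genetic background that differs between animals and switches genes on and off within both groups. With at least 100 counts as on and at most 5 as off, 1 gene qualified, an unnamed transcript on chromosome 5, and 0 pairs of such genes within 10 Mb shared a pattern, because there were no pairs to compare. The search was too strict to test the hypothesis, and no other limits were tried.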
